A study of Mus musculus with 6 samples.

How the data were processed

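Total RNA from cultured primary mammary fibroblasts was labelled with biotin and measured on single-colour Affymetrix arrays, per the labels' protocols. The labels give 3 Pten null and 3 wild type arrays. The fibroblasts were separated from mammary tissue by gravity and grown in serum-containing medium, per the labels' protocols, a step that does not sort cells by a marker. The authors deposited log2 expression values, 1 per probe set and array, and the submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarises the probes of a set on a log scale. The version and settings of RMA are not given in the sources used here, and the log base was taken as 2 because RMA gives log2 values; the deposited values ran from 0.56 to 15.2. Normalization of this kind assumes that most genes do not change, and it compresses differences of dim probe sets.

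The table held 45101 probe sets, 64 of them controls. In the platform annotation used, 34958 had 1 gene symbol, 932 several and 9160, controls left aside, no gene. The 34958 include 13 of the control probe sets, which carry the symbol of a mouse gene, and Gapdh was represented by such a control. Entrez identifiers of 34754 probe sets matched the reference gene table, and 0 symbols needed an update. A gene was represented by the probe set with exactly 1 symbol and the highest mean over the 6 arrays, which gave 18194 genes; no filter on dim probe sets was applied. The 10092 other probe sets were tested apart, and 0 passed while 563 (5.58%) had an unadjusted limma p under 0.05. Of the listed genes 40, Pten among them, were not analysed here.

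The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Pten null minus wild type, no covariate). P-values were adjusted by the method of Benjamini and Hochberg over all genes, and a gene was called at an adjusted p under 0.05. A count at least 2-fold required a log2 fold change of 1 or more in size as well. Errors beside group means are SDs over 3 arrays. For arrays, no sequencing depth exists, and the number of arrays limits the precision.

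The 25 gene lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. The lists held 532 genes, of which 492 were measured: PI3K-AKT pathway components, FOXO target genes, cholesterol and fatty acid synthesis, glycolysis and hypoxia, amino acid synthesis and ER stress, proliferation, p53 targets and senescence, extracellular matrix, matrix proteases, inhibitors and crosslinkers, chemokines and cytokines, interferon response, growth factors and their binding proteins, AP-1, ETS and immediate early genes, TGF-beta and BMP signalling, WNT signalling, ribosomal proteins, and markers of fibroblasts, of myofibroblasts, smooth muscle and pericytes, of macrophages, of lymphocytes, NK and mast cells, of mammary epithelium, of endothelium, of adipocytes, of Schwann cells and glia, and of skeletal muscle. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. The mean of a list per array was compared by an exact permutation test over the 10 splits of 6 arrays, which cannot go below 0.1, two-sided.

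Named genes were S100a4, Ets2, Mmp9, Ccl3, genes past the threshold, the 5 genes of smallest p in each direction where fewer than 5 passed, and from each list the member with the smallest p. Exceptions, chosen after their values were seen, were the 3 next members by p of each list that passed, the members that passed when adjusted over their list alone, Slc41a3, and the neighbouring genes in the closing observations. The alternative settings were the replicate number as a block, filters on the dimmest 25% and 50% of genes, other rules for the probe set of a gene, median centring, quantile and cyclic loess normalization, eBayes with trend and robust options, array weights, a per-gene test without moderation, other thresholds, and leaving out each array in turn. Added after seeing the data were the joint removal of Pten null replicate 3 and wild type replicate 1, and the macrophage marker mean as a covariate.

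The fit was tested on simulated data shaped on this comparison, with 18194 genes, 3 arrays per group and 200 changed genes in each of 20 simulations. It recovered 30.4% of 2-fold, 86.3% of 4-fold, 96.2% of 8-fold and 98.1% of 16-fold changes, with a mean of 9.15 false calls. The changes were placed on genes drawn at random, so these shares do not hold for genes that varied widely between cultures. Ccl3, for example, differed 54.1-fold between the real groups and did not pass (limma adjusted p = 0.263). In 10 simulations with a list shifted by 1 on the log2 scale, camera called the shifted list in 10 and a mean of 0 of the 24 others. The simulated genes were independent of each other, while members of several real lists moved together. This simulation therefore does not show how often camera calls a list wrongly in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.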

Results

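Gene expression was measured in primary fibroblasts grown in culture from the mammary glands of 8-week-old female FVB/N mice. In 3 cultures, called Pten null, both copies of Pten carried loxP sites and Cre recombinase was made under the Fsp promoter, that of the fibroblast gene S100a4. The 3 wild type cultures carried the loxP sites without Cre. Pten encodes a lipid phosphatase that opposes PI3-kinase signalling, and the comparison asks which genes differ in fibroblasts when it is deleted. Each culture was measured on a single-colour Affymetrix array, and 18194 genes were compared. The median log2 value of an array lay between 4.49 and 4.68, and the small number of arrays, 3 per group, limits the precision. The labels call the replicates biological; whether each came from separate mice is not given in the sources used here, so p-values measure the spread between these cultures. Pten itself was not analysed here, so the genotype labels were not checked by its own level.

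Efs, an adaptor protein of the Cas family that binds Src kinases, fell in the Pten null cultures. Its log2 expression was 5.48 ± 0.16 (SD, n = 3) in Pten null and 7.91 ± 0.09 (SD, n = 3) in wild type cultures, a log2 fold change of −2.43 with a standard error of 0.15 and a limma adjusted p of 0.0288. The next lower genes by p, none of which passed, were Igf1, Limch1, Prelp and Tshz2. Igf1, insulin-like growth factor 1, had 9.11 ± 0.17 against 11.35 ± 0.25 (limma adjusted p = 0.0615), and Prelp, a small leucine-rich proteoglycan of the matrix, had 5.90 ± 0.46 against 10.06 ± 0.74 (limma adjusted p = 0.108). Limch1 had a log2 fold change of −1.49, with its 3 other probe sets at −0.69, −0.11 and 0.24, and Tshz2 one of −1.77. Among genes with higher means, also short of the threshold, Bend5 had 5.57 ± 0.38 against 2.82 ± 0.10 (limma adjusted p = 0.0615) and Pdgfb, a growth factor for mesenchymal cells, had 5.93 ± 0.39 against 3.86 ± 0.15 (limma adjusted p = 0.125). The others of the 5 with the smallest p were Chst13, Cdh19 and Ezr, with log2 fold changes of 1.31, 2.46 and 1.34 (0.52 by another probe set of Ezr). Cdh19 is a cadherin of Schwann cell precursors and Ezr links the cell membrane to actin.

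In all, limma called 1 of 18194 genes, lower by 5.39-fold, and 0 higher genes. At an unadjusted p under 0.05 there were 870 higher and 920 lower genes, 1790 together, where chance gives 910. A per-gene test without moderation also called 1 gene, Slc41a3, with a log2 fold change of −0.21; Slc41a3 was picked after its values were seen. The values of the 2 groups did not overlap for 3130 genes, 17.2% of those compared, where chance gives 10%. Of these, 476 differed at least 2-fold, 324 with the higher mean in Pten null cultures and 152 with the lower. Genes that move together can carry a single split of the arrays far from the values given for chance. The other splits were not counted in this way, so the excess over chance was not shown to follow genotype. Leaving out any single array left 0 called genes, and the limma adjusted p of Efs was then 0.0763 to 0.291 at a log2 fold change of −2.37 to −2.52.

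**Figure D1:**
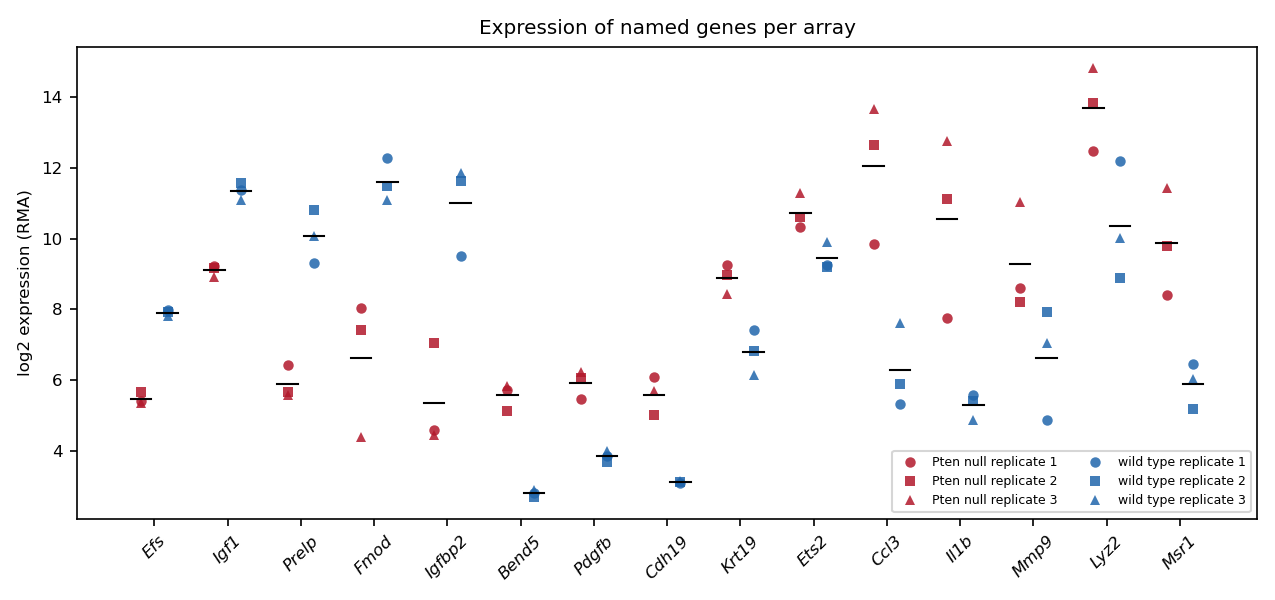
Log2 expression (RMA) of 15 named genes on each array, with red marks for Pten null and blue for wild type cultures, a marker shape per replicate and a black line at each group mean (n = 3). Efs lies at 5.48 in Pten null and 7.91 in wild type cultures, and the other 14 genes did not pass the test over all genes.

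The genes named for their part in the design or in the study's follow-up were not called. S100a4, whose promoter drives Cre, had 13.72 ± 0.17 in Pten null and 13.64 ± 0.90 in wild type cultures (limma adjusted p = 0.973). Ets2, a transcription factor of the ETS family, had 10.73 ± 0.50 against 9.44 ± 0.39, higher in each Pten null array than in any wild type array (limma adjusted p = 0.387). Mmp9, a gelatin-degrading matrix protease, had 9.28 ± 1.53 against 6.62 ± 1.57 (limma adjusted p = 0.470). Ccl3, a chemokine that attracts macrophages and other leukocytes, had 12.04 ± 1.97 against 6.28 ± 1.20 (limma adjusted p = 0.263). Like Ets2, Mmp9 and Ccl3 were higher in each Pten null array than in any wild type array. The study followed up Ets2, Mmp9 and Ccl3, so they are not independent evidence.

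Of the 25 gene lists, macrophage markers had the smallest p by limma's camera test at the preset correlation. With an estimated correlation, glycolysis and hypoxia had a smaller unadjusted camera p (0.0434 against 0.0843). By fry, lists such as PI3K-AKT pathway components had a smaller unadjusted p (0.00783 against 0.0416). All 20 measured macrophage markers had the higher mean in Pten null cultures, with a median log2 fold change of 3.08, and 16 of them did not overlap between groups. The scavenger receptor Msr1 had 9.88 ± 1.51 against 5.90 ± 0.65, the macrophage surface receptor Adgre1 10.30 ± 1.74 against 6.73 ± 0.25, the protease Ctss 10.60 ± 1.14 against 6.98 ± 1.63, and lysozyme gene Lyz2 13.69 ± 1.17 against 10.37 ± 1.68 (SD, n = 3 each). Over all genes 0 of the 20 passed, and 14 passed when adjusted over the list alone. The list was higher by limma's camera test (adjusted p = 3.94e-15), with an adjusted p = 0.413 with an estimated correlation. Its mean per array was 7.74 to 10.5 in Pten null and 5.40 to 7.39 in wild type cultures (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Lymphocyte, NK and mast cell markers had a median log2 fold change of 0.12 (camera adjusted p = 0.202), with Gzma at 2.97 ± 0.14 against 2.59 ± 0.31.

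Chemokines and cytokines were also higher, with 25 of 31 members above wild type, a median log2 fold change of 1.14 and a camera adjusted p of 5.28e-04 (adjusted p = 0.642 with an estimated correlation). Ccl3, Ccl6 and Il1b passed when adjusted over the list alone, and none over all genes. Ccl6 had 11.76 ± 1.25 against 7.74 ± 0.94, Il1b, the inflammatory cytokine interleukin 1 beta, 10.54 ± 2.56 against 5.30 ± 0.37, and Tnf 6.87 ± 1.67 against 3.82 ± 0.50. Wild type replicate 1 had the lowest list mean, 6.52, against 9.14 and 9.25 in the other wild type arrays and 9.32 to 10.5 in Pten null arrays. The median log2 fold change was 1.82 without wild type replicate 2 and 1.81 without wild type replicate 3. Without wild type replicate 1 it was −0.093 (camera adjusted p = 0.936, within a range of 5.88e-06 to 0.936 over 19 alternatives).

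Genes of glycolysis and hypoxia were higher by a small amount, 17 of 19 members with a median log2 fold change of 0.28 (camera adjusted p = 1.02e-05; adjusted p = 0.413 with an estimated correlation). The hypoxia-induced carbonic anhydrase Car9 had 6.09 ± 0.52 against 4.87 ± 0.37 and the oxygen-sensing hydroxylase Egln3 10.34 ± 0.51 against 9.24 ± 0.47. The glycolytic enzymes Hk1 and Pfkp had log2 fold changes of 0.54 and 0.56. None passed over all genes or when adjusted over the list alone. The list mean was 11.77 ± 0.14 in Pten null and 11.40 ± 0.05 in wild type arrays (exact permutation p = 0.1).

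All 24 measured proliferation genes had the higher mean in Pten null cultures, with a median log2 fold change of 0.52 (camera adjusted p = 1.21e-05; adjusted p = 0.642 with an estimated correlation). The replication helicase genes Mcm3, Mcm4 and Mcm5 had log2 fold changes of 0.56, 0.55 and 0.66, and the mitotic kinase Aurkb one of 0.69, with Mcm3 at 0.35 and Aurkb at 0.37 without Pten null replicate 3 and Mcm4 and Mcm5 at 0.83 and 1.0 without wild type replicate 1. None passed when adjusted over the list alone, and 0 of 24 separated the groups. Wild type replicate 1 had a list mean of 9.23, inside the Pten null range of 8.77 to 9.63 (exact permutation p of the list means = 0.3). The median was 0.30 without Pten null replicate 3, 0.32 without wild type replicate 3 and 0.82 without wild type replicate 1, and −0.30 with the macrophage marker mean as a covariate (camera adjusted p = 0.0586, within a range of 2.65e-12 to 0.0586 over 19 alternatives).

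Schwann cell and glial markers were higher in 8 of 10 members, with a median log2 fold change of 0.91 (camera adjusted p = 0.00251; adjusted p = 0.413 with an estimated correlation). An unadjusted limma p under 0.05 was reached by 5 higher members and 1 lower member. The groups did not overlap for 4 higher members and 1 lower member. Only 1 of the 10 lay above the median gene in wild type cultures. Cdh19 had 5.59 ± 0.54 against 3.13 ± 0.03, the neuregulin receptor Erbb3 6.31 ± 0.76 against 3.69 ± 0.76 and the adhesion molecule L1cam 6.89 ± 0.73 against 4.71 ± 0.46. These 3 passed when adjusted over the list alone and none over all genes, and Foxd3, a neural crest factor, had a log2 fold change of 0.93 (0.58 without Pten null replicate 1). Another, dimmer probe set had a log2 fold change of 0.41 for Erbb3 (mean level 2.80) and 0.26 for L1cam (mean level 3.13). The list mean was 6.01 ± 0.25 against 4.94 ± 0.20 (exact permutation p = 0.1).

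Myofibroblast, smooth muscle and pericyte markers went the other way, with 14 of 17 members lower, a median log2 fold change of −0.36 and a camera adjusted p of 5.63e-04 (adjusted p = 0.413 with an estimated correlation). Smooth muscle myosin Myh11 had 5.0 ± 1.51 against 7.95 ± 0.07 and leiomodin Lmod1 5.74 ± 0.38 against 6.77 ± 0.19, and both passed when adjusted over the list alone. Another, dimmer probe set of Myh11 (mean level 3.89) had a log2 fold change of −0.29. Notch3 and Rgs5, both pericyte genes, had log2 fold changes of −1.15 and −1.0, the latter with other probe sets at −1.09, −0.17 and 0.21. Without Pten null replicate 2 Notch3 had −0.79 and Rgs5 −0.61. The median was −0.33 without wild type replicate 1 (camera adjusted p = 0.0696) and −0.098 without both that array and Pten null replicate 3 (0.274), within a range of 1.08e-06 to 0.274 over 19 alternatives.

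**Figure D2:**
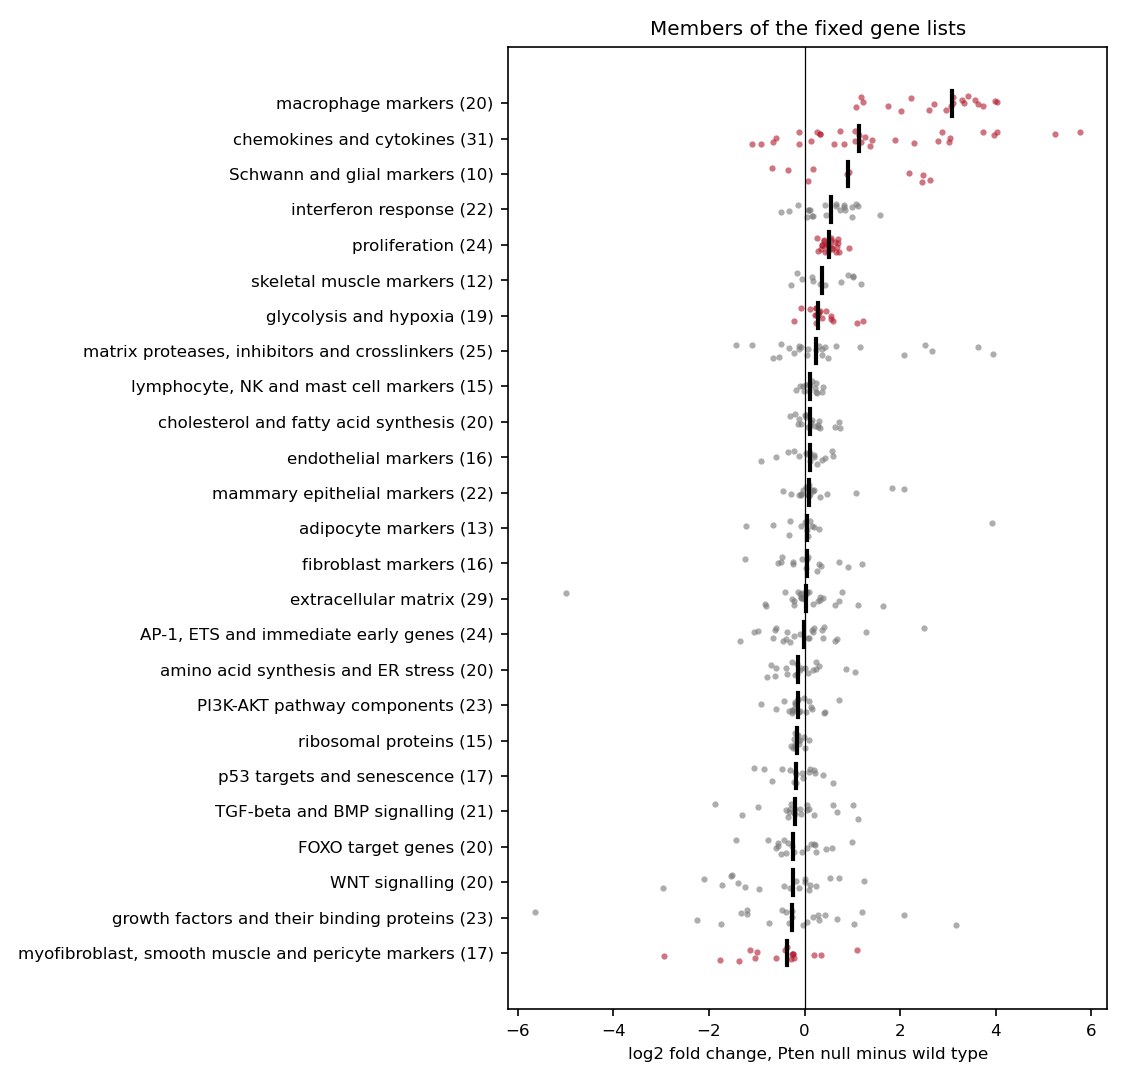
Log2 fold change, Pten null minus wild type, of each measured member of the 25 fixed gene lists, with a black bar at each list's median and the number of members in brackets. The 6 lists in red passed limma's camera test with the preset correlation, from macrophage markers (median 3.08) to myofibroblast, smooth muscle and pericyte markers (median −0.36), and 0 passed with an estimated correlation.

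These 6 of 25 lists were the ones that passed. With an estimated correlation 0 of 25 passed, and limma's fry test, which asks whether a list moves one way on balance, also passed 0. Fry's separate test for change in either direction passed 4 of 25. They were Schwann and glial markers (fry adjusted p = 0.00198), glycolysis and hypoxia (0.0409) and the 2 lists described next. Macrophage markers did not pass it (0.174). Of the 10 splits of the 6 arrays into 3 and 3, 8, the real one included, gave 6 or more passing lists. The exact permutation p of the list means was also 0.1 for PI3K-AKT pathway components and WNT signalling, which did not pass camera.

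Growth factors and their binding proteins did not pass as a list moving one way (13 lower and 10 higher; median −0.26, camera adjusted p = 0.188), but fry's test for change in either direction gave an adjusted p of 0.00163. When adjusted over the list alone 6 of 23 passed. Igf1 (−2.24 on the log2 scale), Igfbp2 (−5.63), Mdk (−1.20) and Fgf10 (−1.32) were lower, and Igfbp5 (3.16) and Pdgfb (2.07) higher. Igfbp2 lay at 4.45 to 7.06 in Pten null and 9.52 to 11.86 in wild type arrays, with a log2 fold change of −6.47 without Pten null replicate 2, and Igfbp5 had 11.64 ± 0.92 against 8.48 ± 0.58, with another probe set at 1.89. Both encode proteins that bind insulin-like growth factors. The median of the list was −0.10 without Pten null replicate 3 and −0.090 without wild type replicate 2. AP-1, ETS and immediate early genes were divided in the same manner, with 12 higher and 12 lower, a median of −0.0082 that was 0.011 under cyclic loess normalization, a camera adjusted p of 0.371 and a fry adjusted p of 0.00198 for change in either direction. Ets1, Ets2 and Atf3 were higher (0.68, 1.29 and 2.49), and Fos, Egr1, Ier2, Dusp1 and Myc lower (−1.05, −1.35, −0.98, −0.60 and −0.44), each passing when adjusted over the list alone and none over all genes. The 3 other probe sets of Ets1 had 0.37, 0.30 and 0.18. Without wild type replicate 1 the median of this list was −0.21 (camera adjusted p = 0.00626, within a range of 1.48e-04 to 0.877 over 19 alternatives).

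Extracellular matrix genes had a median log2 fold change of 0.024 and a mean of −0.057 (camera adjusted p = 0.729). Within them Fmod, fibromodulin, had 6.62 ± 1.94 against 11.61 ± 0.60 and Postn, periostin, 14.17 ± 0.07 against 13.54 ± 0.08; these were the 2 members that passed when adjusted over the list alone. Matrix proteases, inhibitors and crosslinkers had a median of 0.23 (camera adjusted p = 0.293), with Mmp23 (−1.10) and Adamts5 (−1.43) passing over the list alone. In TGF-beta and BMP signalling (median −0.20, camera adjusted p = 0.316) the inhibitory Smad6 had 6.79 ± 0.73 against 8.67 ± 0.15 and passed over the list alone. Without Pten null replicate 1 this list had a median of −0.31 (camera adjusted p = 0.0462, the lowest of a range up to 0.824). Its median was −0.0285 without Pten null replicate 2. WNT signalling had a median of −0.25 (camera adjusted p = 0.160), which was −0.097, −0.11 and −0.13 without Pten null replicate 3, wild type replicate 2 or Pten null replicate 1, and its antagonist Sfrp1 had 8.62 ± 1.02 against 11.58 ± 0.99.

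PI3K-AKT pathway components had 16 of 23 members lower and a median log2 fold change of −0.14 (camera adjusted p = 0.202), with the receptor Igf1r at 8.91 ± 0.06 against 9.51 ± 0.25, a log2 fold change of −0.60, and its 4 other probe sets at −0.06, −0.09, −0.39 and −0.89. Without Pten null replicate 3 the list's median was −0.081. FOXO target genes had 12 of 20 lower and a median of −0.24 (camera adjusted p = 0.106), with Selenop at −0.55. Cholesterol and fatty acid synthesis had a median of 0.12 (camera adjusted p = 0.188; Dhcr7 0.71), amino acid synthesis and ER stress −0.13 (0.371; Pdia4 −0.61, with another probe set at 0.47), p53 targets and senescence −0.17 (0.316; Cdkn2b −0.86, and −0.41 without Pten null replicate 3) and ribosomal proteins −0.15 (0.0708; Rpl7 −0.21, and −0.10 without wild type replicate 1). Single arrays moved several of these lists past the threshold. Without wild type replicate 1, cholesterol and fatty acid synthesis had a median of 0.40 (camera adjusted p = 5.25e-06, range over alternatives 7.93e-09 to 0.899) and p53 targets and senescence one of −0.44 (3.49e-04, range 7.15e-05 to 0.928). Without Pten null replicate 3, the cholesterol list had 0.28 and FOXO target genes −0.13 (camera adjusted p = 0.0308 for both; FOXO range 0.0213 to 0.219). Ribosomal proteins had −0.23, −0.21 and −0.20 without wild type replicate 3, wild type replicate 2 or Pten null replicate 1 (camera adjusted p = 0.0152, 0.0171 and 0.0304, range 0.0115 to 0.767). The ribosomal median was −0.056 without wild type replicate 1 (camera adjusted p = 0.767).

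With all 6 arrays, the other cell type markers did not pass as lists. Fibroblast markers had a median log2 fold change of 0.045 (camera adjusted p = 0.563, in the lower direction), with Pdgfra, a fibroblast receptor, at 11.75 ± 0.25 against 12.29 ± 0.13. Mammary epithelial markers had a median of 0.083 (camera adjusted p = 0.160), and Krt19 alone passed over the list, at 8.89 ± 0.41 against 6.80 ± 0.63. Without wild type replicate 1 the epithelial median was 0.20 (camera adjusted p = 0.0372, range over alternatives 0.0167 to 0.667), and without wild type replicate 3 it was 0.031. Adipocyte markers had a median of 0.054 (camera adjusted p = 0.924), and Cd36, a fatty acid transporter also made by macrophages, alone passed over the list, at 9.02 ± 1.78 against 5.10 ± 0.65. Endothelial markers had a median of 0.11 (camera adjusted p = 0.371; Cldn5 0.60) and skeletal muscle markers 0.37 (camera adjusted p = 0.211; Myod1 0.75, with another probe set at −0.56). Without Pten null replicate 1 the skeletal muscle median was 0.86 (camera adjusted p = 0.0137, range over alternatives 2.61e-04 to 0.963), and without Pten null replicate 3 it was 0.074. The endothelial median was 0.0195 without wild type replicate 3 and 0.204 without Pten null replicate 2.

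Interferon response genes varied between cultures of both groups. Their mean was 5.22 in wild type replicate 1 and 6.80 in Pten null replicate 2, and 9.27 to 9.35 in the other 4 arrays, so the median log2 fold change of 0.55 did not pass (camera adjusted p = 0.327; exact permutation p = 1). Rsad2, an antiviral enzyme, had 8.38 ± 1.58 against 6.81 ± 2.66, a log2 fold change of 1.58 that was 0.055 without wild type replicate 1. Without wild type replicate 1 the list's median was −1.02 (camera adjusted p = 0.00682, within a range of 1.20e-04 to 0.990 over 19 alternatives). It was 1.34, 1.31 and 1.09 without Pten null replicate 2, wild type replicate 3 or wild type replicate 2 (camera adjusted p = 0.00221, 0.0194 and 0.0204). Wild type replicate 1 correlated with the other wild type arrays at 0.965 and 0.966 across genes, against 0.992 between those arrays, and at 0.973 with Pten null replicate 2. Genes are not independent replicates.

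**Figure D3:**
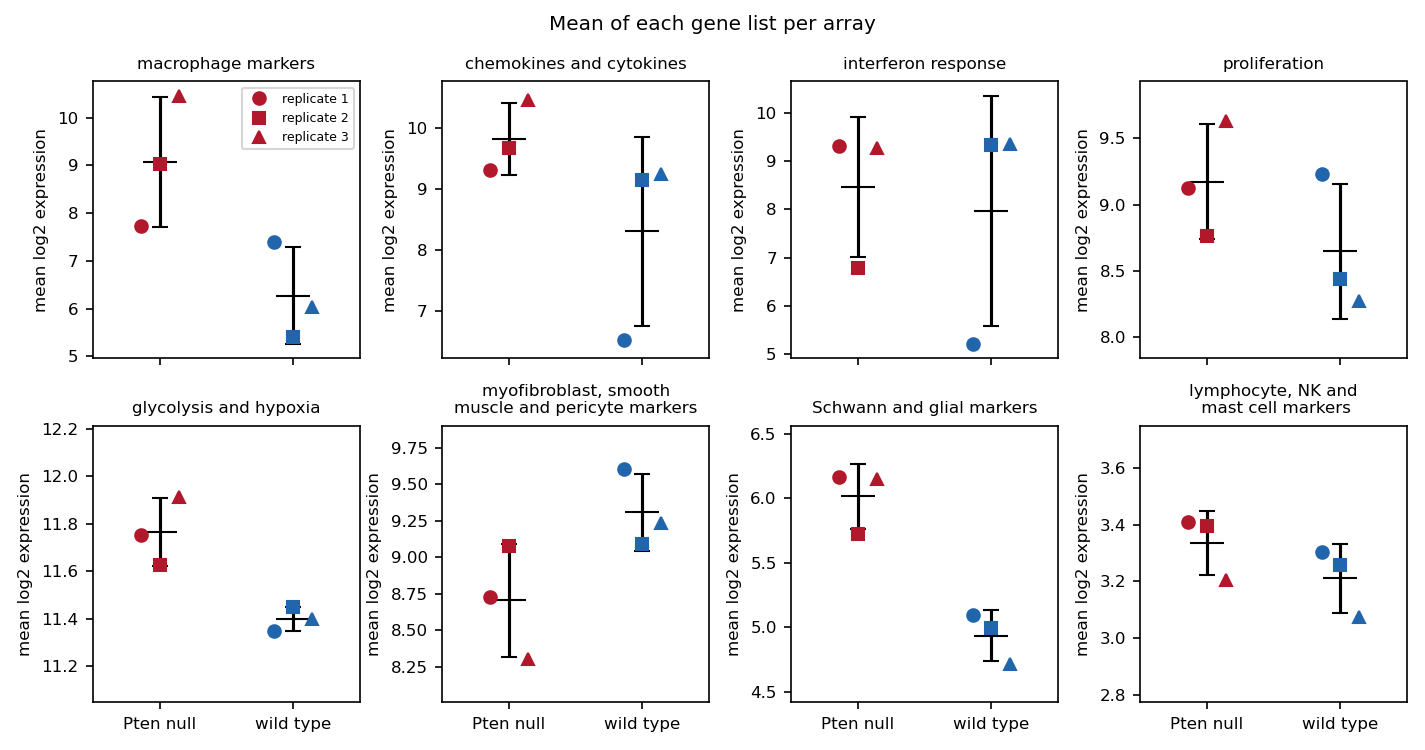
Mean log2 expression of the members of 8 gene lists on each array, red for Pten null and blue for wild type, with a marker shape per replicate and the group mean ± SD in black (n = 3). Macrophage markers lay at 7.74 to 10.5 in Pten null and 5.40 to 7.39 in wild type arrays, and the interferon list was lowest in wild type replicate 1 (5.22) and Pten null replicate 2 (6.80).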

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

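The alternatives were fixed before the data were examined, except the joint removal of Pten null replicate 3 and wild type replicate 1 and the macrophage covariate, which were chosen after the result was seen. The call of Efs, but not its size, depended on the setting: its log2 fold change was −2.59 to −2.34 over 21 alternatives, while 0 genes, and 0 at least 2-fold, passed with any single array left out, with the replicate block, with every probe set tested, at an adjusted p under 0.01, without both doubted arrays, or with the macrophage covariate. Removing arrays or adding terms leaves fewer residual degrees of freedom, and testing more probe sets widens the adjustment. The limma adjusted p of Efs was 0.188 with the block (1407 genes at an unadjusted p under 0.05), and the block called 6 lists. Same-numbered arrays deviated from their group means with correlations of −0.142, −0.293 and 0.152. These gave no sign that the numbers pair the cultures, but so few arrays cannot exclude a pairing. Counts were 2 and 2 without the dimmest 50% of genes and with trend and robust options (Efs and Igf1 in both), 6 and 6 with array weights, and 3 and 3 at an adjusted p under 0.1; the test without moderation gave 1, and 0 at least 2-fold. The count of passing lists was 0 with an estimated correlation, 0 with fry, 14 without both doubted arrays and 7 to 9 with single arrays left out. The log offset alternative was not run, because the values were already log2.

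The macrophage, glycolysis and Schwann lists kept their direction and passed camera in every setting with the preset correlation that gave them a value. Wild type replicate 1 decided the chemokine list (its range with single arrays left out was −0.093 to 1.82), and array weights, which gave that array 0.267, brought its median to 0.097 (camera adjusted p = 0.196). Other medians that changed sign with single arrays left out ran from −0.103 to 0.139 (extracellular matrix), −0.210 to 0.165 (AP-1, ETS and immediate early genes), −0.116 to 0.069 (fibroblast), −0.036 to 0.400 (cholesterol), −0.090 to 0.057 (adipocyte), −0.234 to 0.133 (ER stress), −0.0067 to 0.294 (proteases), −1.02 to 1.34 (interferon) and −0.443 to 0.058 (p53), and S100a4 from −0.444 to 0.352. Reversed log2 values were −0.065 for extracellular matrix with the mean of all probe sets and 0.011 for AP-1, ETS and immediate early genes with cyclic loess. With array weights they were 0.081 for ER stress, −0.705 for interferon, −0.103 for fibroblast, −0.0069 for adipocyte and −0.318 for S100a4. Without both doubted arrays they were 0.149 for ER stress, −0.132 for chemokines, −1.27 for interferon, −0.165 for fibroblast, −0.032 for adipocyte, 0.024 for ribosomal proteins, −0.617 for Rsad2 and −0.354 for S100a4. With the macrophage covariate they were −0.140 for cholesterol, −0.303 for proliferation, 0.248 for p53, −0.120 for extracellular matrix, 0.218 for growth factors, 0.195 for AP-1, ETS and immediate early genes, 0.096 for TGF-beta, −0.753 for skeletal muscle, −0.021 for Aurkb, 0.088 for Cdkn2b, −0.175 for Mcm3, −0.115 for Mcm5 and −0.441 for Myod1. The macrophage mean did not overlap between the groups (7.74 to 10.5 in Pten null and 5.40 to 7.39 in wild type arrays). The values with this covariate therefore separate it poorly from genotype. Besides reversals, 32 list medians gained a camera call and 3 lost it. The lost calls were chemokines with array weights, and myofibroblast markers without wild type replicate 1 or without both doubted arrays (−0.098). Gained calls with single arrays left out are in the account of each list. With array weights cholesterol, p53 and AP-1, ETS and immediate early genes gained one, with the mean of all probe sets WNT signalling, with median centring, cyclic loess or an adjusted p under 0.1 ribosomal proteins, and with the macrophage covariate ER stress (−0.376) and interferon (3.14). Without both doubted arrays cholesterol, p53, AP-1, FOXO, extracellular matrix, WNT, growth factor, lymphocyte and epithelial lists gained one. The cause was not tested. Of the other values, 394 list medians and 1532 single-gene values kept their direction and side of the threshold.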

Other observations

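The counts over splits of the arrays, the test of chemokines against macrophage markers, the mislabelling test and the neighbour test were planned before their results were seen, and the other tests here were chosen only after the result was seen.

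Several of the genes with the smallest p lay next to each other in the mouse gene order. The myeloid C-type lectins Clec4n, Clec4d and Clec4e, which are neighbours, had log2 fold changes of 4.08, 3.72 and 4.30, and the neighbouring chemokines Ccl6 and Ccl3 had 4.03 and 5.76. The proteoglycans Prelp and Fmod, also neighbours, had −4.16 and −4.99, and Efs lay beside Slc22a17, which had −0.68. The adjacent genes Igfbp2 and Igfbp5 went in opposite directions, −5.63 and 3.16. Of these only Efs passed limma's test over all genes. Among the 200 genes of smallest p there were 7 neighbouring pairs of one direction, against a 95th percentile of 3 in 1000 random sets of genes (one-sided permutation p = 0.002). A candidate explanation is shared regulation of neighbours, but gene families expressed by one cell type, as in the lectin cluster, could give the same count, and no test here separates the 2.

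For the higher macrophage markers, the lowest median log2 fold change under median centring, quantile or cyclic loess normalization was 3.07. These scalings were applied to values that the authors had already normalized. The result argues against scaling differences left between the deposited arrays, but cannot test the authors' own normalization, which was not undone. A lower share of fibroblasts stays open: the lower quartile of the macrophage members minus the highest upper quartile among 6 other cell type lists was −0.210, set by Schwann and glial markers (2.39). The other upper quartiles, from 0.16 for adipocyte to 0.94 for skeletal muscle markers, were lower, but most members of these lists lay below the median gene in wild type cultures, except 7 of 13 adipocyte genes, whose levels there could hide a small share of adipocytes. Unequal shares of macrophages remain a candidate explanation: within groups the markers moved together, with a mean pairwise correlation of 0.766 against a 95th percentile of 0.0829 in random lists, and abundant macrophage genes were high (Lyz2 13.69 in Pten null cultures, Cd14 11.68), though lists of other kinds moved together as closely (estimated correlation 0.940 for interferon, 0.795 for proliferation and 0.770 for ribosomal proteins). Of the 20 markers 8 lay above the median gene in wild type cultures, 0 are on another list, and gravity separation does not remove macrophages by a marker; whether Pten deletion raised their number or their survival was not tested.

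The chemokine list may in part come with macrophages, which was not settled: Spearman's rho across its 31 members between the within-group slope on the macrophage mean and the fold change was 0.315 (permutation p = 0.0853, genes not being independent replicates). With the macrophage mean as a covariate the list stayed higher and called (median 2.21), and 23 of 31 slopes were below 0. The macrophage mean itself did not overlap between the groups, so a fit with both terms separates it poorly from genotype. Without wild type replicate 1 only 7 slopes were below 0 and the list was not higher (median −0.0933), so this single array decides both and the sources cannot be told apart.

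Wild type replicate 1 stood apart from the other wild type arrays. The tables argue against RNA degradation, since its 3′ minus 5′ signal of the actin and Gapdh controls was −0.200, inside the range of −0.212 to −0.147 on the other arrays. Its low interferon genes were shared with a culture of the other genotype: this array and Pten null replicate 2 were the 2 lowest for 22 of 22 members. The array lay nearer to the wild type mean for 44.5% of 200 genes chosen without it. The rule written beforehand took a share of over 50% nearer to the Pten null mean as the mark of a mislabelled culture, and the array met it. It did not meet the stricter limit applied here, a wild type share more than 2 standard errors under 50%. The binomial standard error of 3.54 points takes genes moving together as independent and so is too small. Pten null replicate 1 lay nearer to its own group for 51% in the same test. A mislabelled Pten null culture therefore cannot be told apart from a wild type one here. The list means of wild type replicate 1 lay on the wild type side for Schwann and glial markers (5.10, against 5.73 to 6.17 in Pten null arrays) and glycolysis (11.35, against 11.63 to 11.91), as did Efs (7.99, against 5.37 to 5.67), but among the Pten null arrays for proliferation (9.23, against 8.77 to 9.63). Efs was called with this array counted as wild type, so its side was partly fixed by that call. The Schwann and glycolysis lists passed camera at the preset correlation with or without this array. No biological explanation was tested.

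Chance was counted over the 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05. The real split gave 1 called gene (1 at least 2-fold) and the highest other split 0, so 1 of 10 splits gave as many. For gene lists the real split gave 6 and the highest other 10, and 8 of 10 splits gave 6 or more.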
